A study of Mus musculus with 9 samples.

How the data were processed

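White adipose tissue was taken from male C57BL/6JHamSlc-ob/ob mice, 6 weeks old at arrival and acclimatized for 1 week, after 42 days (6 weeks) of daily oral vehicle or extract of Vigna umbellata at 50 or 100 mg/kg. Per the labels, RNA from 3 mice per group was extracted with ISOGEN, and 100 ng was used for Clariom S mouse arrays hybridized for 16 h at 45 °C. In all, 9 arrays were thus available, 3 per group. Wild-type arrays are mentioned in the design but are not in the series and were not analysed here.

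The authors deposited gene-level log2 signals of all 9 arrays made with Transcriptome Analysis Console 4.0.2, which the design text calls SST-RMA and the processing notes RMA. A deposited workbook holds a second set of log2 signals per array, group averages in log2, the p-value and FDR of the authors' F test, and a filtered comparison of 100 mg/kg with vehicle. Its fold change, per the file headers, is a linear score in which a lower value is written as minus the inverse. Study criteria stated by the authors were an unadjusted p under 0.05 in a one-way analysis of variance with empirical Bayes and a fold over 1.1, with arrays kept at a positive versus negative control area under the curve of at least 0.7.

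Median signal and control separation were close on all arrays: median log2 5.73 to 5.81 and an area under the curve of 0.827 to 0.862. The SD of the log2 signals differed by group: 3.11 to 3.14 in vehicle, 3.16 to 3.22 at 50 mg/kg and 3.20 to 3.25 at 100 mg/kg. Positive control medians were 9.19 to 9.34 in vehicle, 9.15 to 9.31 at 50 mg/kg and 9.39 to 9.51 at 100 mg/kg. Every treated array thus had a wider spread of signals than every vehicle array. Correlations were 0.979 to 0.987 within groups and 0.969 to 0.989 between groups. Scale values stop at 19.92, and 15 probe sets had a mean over 19.5. Control features (6640 of 28846: 5222 negative, 1324 positive and 23 background controls among them) were removed, leaving 22206 probe sets, of which 21367 carried 1 gene symbol, 836 several and 3 none. Symbols came from the deposited differential table, since 2 symbols of the signal sheet had been altered. Genomic spans from the RefSeq gene table were found for 20755 of them. A genomic span is not a transcript length.

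All comparisons were made on the series values in 1 limma fit (limma 3.58.1, R 4.3.3, statmod 1.5.0) of all 9 arrays with a mean per group, no covariate and empirical Bayes moderation (6 residual and 4.97 prior degrees of freedom). Contrasts were 50 mg/kg minus vehicle, 100 mg/kg minus vehicle, 100 minus 50 mg/kg and the mean of both doses minus vehicle, with a moderated F test over the 3 groups. P-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets. The number of arrays limits the precision: an exact permutation test of 3 against 3 arrays cannot go below p = 0.1. The lists, the comparisons and all alternatives but 3, named below, were fixed before the data were examined.

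Gene lists (40, of adipocyte and metabolic pathways, immune, stromal and neighbouring cell types, and handling) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Members were also counted by the study criteria, by adjusted p, and adjusted over the list alone.

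Genes were named by a rule fixed in advance. It named (a) genes at adjusted p < 0.05, at most 10 higher and 10 lower per comparison by absolute difference. Part (b) named up to 10 higher and 10 lower genes by the study criteria with the 3 arrays of each group apart, a mean signal over the median of all probe sets (5.75), 1 symbol and no predicted, clone or receptor segment name. Part (c) named up to 4 members of lowest p in each list described, and (d) 17 genes always: Lep, Adipoq, Pparg, Fasn, Scd1, Lipe, Pnpla2, Ucp1, Ppargc1a, Slc2a4, Adgre1, Cd68, Ccl2, Tnf, Il6, Col1a1 and Col6a3. Of several probe sets the one of highest mean was used. Not every gene that the rule names is printed.

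The fit was tested on simulated data with the spread of these arrays. Differences of 0.5 were recovered in 0 to 2% of 50 probe sets, of 1 in 20 to 24%, of 2 in 90 to 100% and of 3 in 98 to 100%, with 7 to 9 false calls. Camera with the preset correlation called the raised list in 50 of 50 simulations and 6 of 1900 unchanged lists, on genes simulated as independent.

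Alternatives were each array left out in turn, quantile normalization, median centring, the workbook's signals, removal of dim probe sets, each comparison on its own groups, array weights, trend and robust moderation, no moderation, a fold over 1.5, a block of replicate numbers, the hepatocyte level as covariate, the 3 arrays of high hepatocyte signal left out, and removal of the trend with span. The last 3 were added after the data were seen. Other splits of the arrays were counted (10 for 3 against 3, 84 for both doses, 100 drawn of 280 for 3 groups). That draw was given its own seed after earlier draws had given other counts. Some tests of explanations were replaced after their values were seen, as stated with the results. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.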

Results

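White adipose tissue of male leptin-deficient (ob/ob) mice was profiled after 42 days of oral gavage with vehicle or with Vigna umbellata extract (VE) at 50 or 100 mg/kg body weight, with 3 arrays per group. The labels give separate samples of each group, and the p-values below measure the spread between these samples. Values are log2 signals as mean ± SD of 3 arrays, differences are log2 with their standard error (SE) from limma, and adjusted p-values cover all 22206 probe sets or all 40 gene lists. In what follows, the study criteria are an unadjusted p under 0.05 with a fold over 1.1, for which chance alone gives 1110.3 probe sets. A gene is said to have risen or fallen only where it passed adjusted p < 0.05.

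At 100 mg/kg, 38 probe sets rose and 2 fell against vehicle (limma, n = 3 per group). The largest change was in Myeov2, now called Cops9, a subunit of the COP9 signalosome, from 9.66 ± 0.35 in vehicle to 14.19 ± 0.10 (difference 4.53, SE 0.26, 23.1-fold, adjusted p = 4.4e-05). Dad1, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum, rose from 15.03 ± 0.49 to 18.05 ± 0.25 (3.01, SE 0.31, adjusted p = 0.00378). Atp5g1, which encodes the c-ring subunit of ATP synthase, rose from 9.30 ± 0.38 to 12.27 ± 0.61 (2.97, SE 0.36, adjusted p = 0.00995). Dusp10, a phosphatase that inactivates the stress kinases p38 and JNK, fell from 12.33 ± 0.36 to 10.95 ± 0.21 (-1.38, SE 0.23, adjusted p = 0.0442), a call kept in 4 of 21 alternative fits and lost without single arrays (adjusted p up to 0.237).

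**Figure D1:**
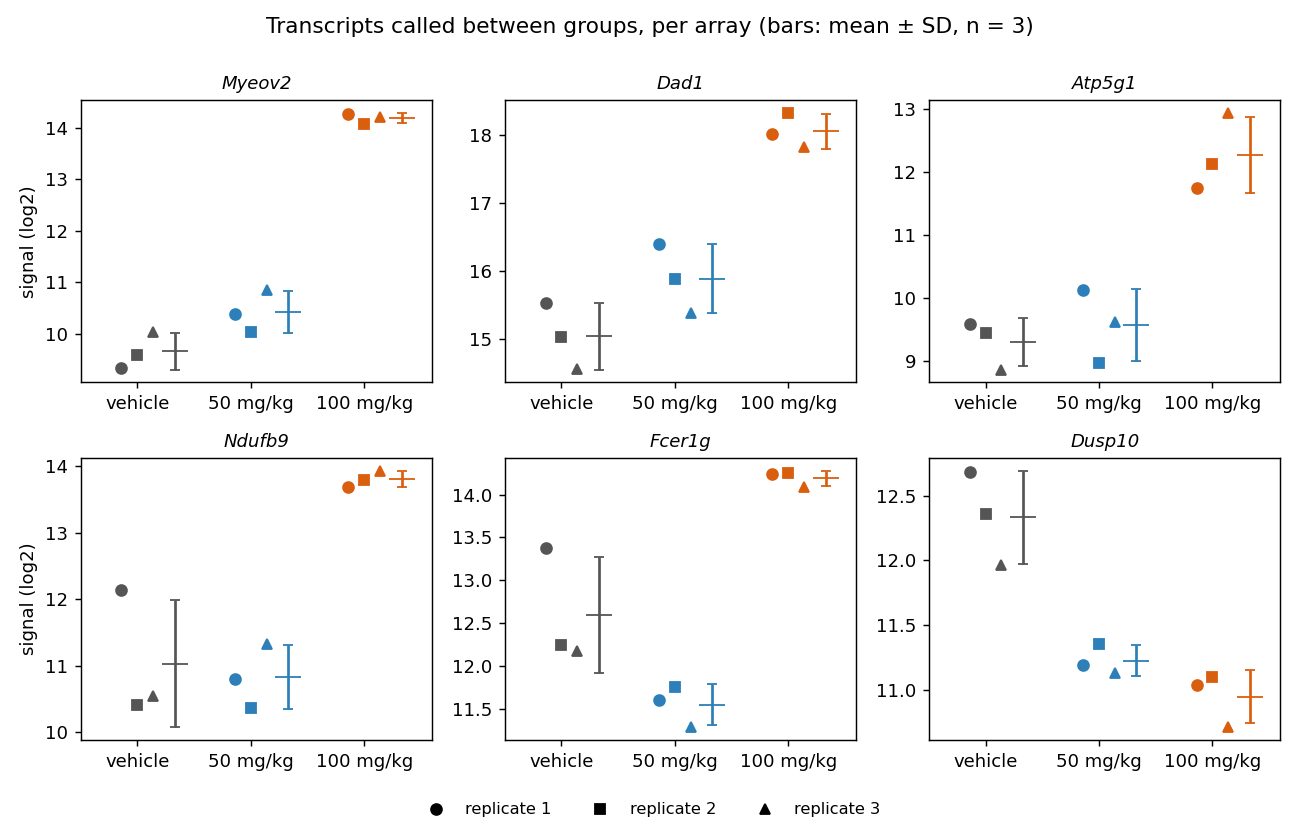
Signal of 6 transcripts on each array, with the mean and SD of each group (n = 3). Myeov2, Dad1, Atp5g1, Ndufb9 and Dusp10 were called between 100 mg/kg and vehicle, and Fcer1g between the 2 doses.

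Further calls at 100 mg/kg were Ndufb9 (2.77, SE 0.41) and Ndufc1 (2.48, SE 0.25), accessory subunits of complex I, and Minos1, now Micos10, a core part of the complex that shapes mitochondrial cristae (2.61, SE 0.23). Atp5d, the delta subunit of ATP synthase (2.55, SE 0.36), and Mrpl33, a protein of the mitochondrial ribosome (2.33, SE 0.30), rose as well. So did Rpl28 of the cytosolic ribosome (2.42, SE 0.39) and Ppdpf, a regulator of exocrine pancreas development (2.84, SE 0.26). Their adjusted p-values ran from 0.0022 for Ppdpf and Minos1 to 0.041 for Rpl28. Mt4, a metallothionein of stratified epithelium, was the other call (6.54 ± 0.17 to 5.12 ± 0.29), with a signal at 100 mg/kg below the median of the negative controls on each array, so that the size of its change is not known.

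Respiratory chain genes were the list of lowest adjusted p at the preset correlation. Of 42 oxidative phosphorylation genes, 23 were higher by the study criteria and none lower, 4 rose at adjusted p < 0.05, and 23 were higher when adjusted over the list alone. The 4 were Atp5g1, Atp5d, the complex I subunit Ndufs8 (1.91, SE 0.27) and the catalytic ATP synthase subunit Atp5b (1.39, SE 0.20), and of 21 alternative fits Ndufs8 kept its call in 13 and Atp5b in 8. Per array, the median of the list lay at -0.28 ± 0.36 in vehicle, -0.25 ± 0.23 at 50 mg/kg and 0.48 ± 0.18 at 100 mg/kg around the mean of all 9 arrays. The list was higher by a median of 0.68 (adjusted p = 3.08e-21 with the preset correlation of 0.01, adjusted p = 0.259 with an estimated correlation).

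Cytosolic ribosomal proteins had a median difference of 0.58 (adjusted p = 2.58e-11, adjusted p = 0.521 with an estimated correlation). Of their 30 genes 13 were higher and 1 lower by the study criteria, and 9 were higher adjusted over the list alone. Rpl15, a protein of the large subunit, rose (1.74, SE 0.27, adjusted p = 0.035, kept in 8 of 21 alternative fits), while Rpl19 did not pass (1.30, SE 0.24, adjusted p = 0.0849). Respiratory chain and ribosomal genes are short. Among genes with a mean log2 signal over 8, those with a genomic span under 2 kb had a median difference of 0.35 (182 genes) against -0.01 for those over 100 kb (898 genes). At 50 mg/kg against vehicle the trend ran the other way, with -0.17 for the short and 0.18 for the long genes. Between the doses it was larger, with 0.50 and -0.21, so lists of short or long genes shift with it in every comparison.

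Glucocorticoid-induced genes were higher by a median of 0.88 at 100 mg/kg (adjusted p = 2.17e-07, adjusted p = 0.272 with an estimated correlation). Of these 18 genes 7 met the study criteria, 2 when adjusted over the list alone, among them the transcription factor Cebpd (1.64, SE 0.38) and the metal-binding Mt2 (1.58, SE 0.46) and Mt1 (2.84-fold). Branched-chain amino acid breakdown had a median of 0.37 (adjusted p = 1.56e-05, adjusted p = 0.259 with an estimated correlation), with 4 of 21 genes by the study criteria and 2 adjusted over the list alone. Its strongest members were Hsd17b10, of isoleucine breakdown (1.74, SE 0.36), and Mcee, of propionate handling (1.47, SE 0.35).

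Fatty acid oxidation had a median of 0.26 (adjusted p = 0.000134, adjusted p = 0.193 with an estimated correlation), with 4 of 24 genes by the study criteria and 1 adjusted over the list alone. The carnitine carrier Slc25a20 led it (0.95, SE 0.19). For antioxidant and NRF2 target genes the median was 0.22 (adjusted p = 0.00108, adjusted p = 0.623 with an estimated correlation), with 6 of 30 by the study criteria and 3 adjusted over the list alone, among them thioredoxin Txn1 (1.21, SE 0.27) and glutathione peroxidase Gpx1 (1.01, SE 0.23).

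Adipocyte identity genes had a median of 0.18 at this dose (adjusted p = 0.00511, adjusted p = 0.597 with an estimated correlation). Of these 25 genes 5 met the study criteria and 2 adjusted over the list alone, and the largest difference was in the adipokine resistin, Retn (13.74 ± 1.76 to 16.81 ± 0.56, 3.07, SE 0.68, adjusted p = 0.171). Fatty acid and triglyceride synthesis had a median of 0.16 (adjusted p = 0.0244, adjusted p = 0.259 with an estimated correlation), with 2 of 23 genes by the study criteria and 1 adjusted over the list alone. That list was led by the lipogenic regulator Thrsp (1.67, SE 0.36). Hepatocyte genes had a median of 0.90 (adjusted p = 0.0116, adjusted p = 0.937 with an estimated correlation), and 1 of 21 met the study criteria. The list's direction turned without the third 100 mg/kg array, which alone held high hepatocyte transcripts in its group.

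Among lower transcripts at 100 mg/kg that met the study criteria with all 3 arrays below vehicle and a mean signal over the median of all probe sets, none but Dusp10 passed adjustment. They included the acute-phase protein Saa2 (-2.00, SE 0.57, with a signal at 100 mg/kg near the negative controls), the clock activator Arntl (-1.32, SE 0.34), the NF-kB subunit Rela (2.14-fold lower) and Lrrc32, which presents latent TGF-beta (-1.08, SE 0.29). The splicing factor Sf1 (-1.03, SE 0.29), the vasodilator Adm (-1.01, SE 0.34), the Notch modifier Lfng (-0.97, SE 0.34) and Morn1, a MORN-repeat protein (-0.96, SE 0.23), were also lower. A complex I subunit outside the list, Ndufs7, was higher (2.51, SE 0.44, adjusted p = 0.0658).

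Of the 9 lists called at 100 mg/kg, 4 were lost without some single array. Without the third 100 mg/kg array the median was 0.05 for adipocyte identity (adjusted p = 0.249) and 0.09 for antioxidant genes (0.329), and without the third vehicle array 0.08 (0.0639) and 0.19 (0.0837). Lipid synthesis was lost without the first vehicle array (0.191) or the first 100 mg/kg array (0.0542), and the hepatocyte list also without the first vehicle array (0.474). The ribosomal median was 0.36 without the second vehicle array, and the list stayed called. Without the third vehicle array the difference was -1.15 for Saa2 and -0.87 for Arntl.

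In all, 969 probe sets were higher and 757 lower by the study criteria, 1288 of them over 1.5-fold. Higher ones were 56.1% of all and 80.6% of the 911 left without dim probe sets. The 3 arrays of each group did not overlap for 12.7% of all probe sets, where 10% is chance. The count of 40 calls moved with single arrays: it was 185 without the first vehicle array and 9 to 31 without any other array, the lowest without the second vehicle array. Myeov2 passed in each of these fits.

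At 50 mg/kg no probe set passed adjustment (lowest adjusted p = 0.694), and 730 were higher and 852 lower by the study criteria (1160 over 1.5-fold). The balance depends on dim probe sets: 46.1% of these were higher, against 69.3% of the 681 left without the dimmer ones. Liver transcripts were the list of lowest adjusted p at the preset correlation. Of 21 hepatocyte genes 8 were higher by the study criteria, with a list median of 1.84 (adjusted p = 5.63e-10, adjusted p = 0.650 with an estimated correlation). The largest differences were in Hpd, of tyrosine breakdown (10.53 ± 0.72 to 13.92 ± 1.49, 3.39, SE 1.11), the tyrosine aminotransferase Tat (3.15, SE 1.12), the apolipoprotein Apoa1 (3.02, SE 1.04) and the urea cycle enzyme Cps1 (2.76, SE 1.04). Medians of the hepatocyte list per array were -1.67, -0.63 and -0.67 in vehicle, 2.59, -0.53 and 1.01 at 50 mg/kg, and -1.85, -0.07 and 1.77 at 100 mg/kg.

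Other transcripts among the 10 highest at 50 mg/kg with all 3 arrays above vehicle were the bile acid enzyme Cyp7a1 (2.93, SE 0.97), the oxidase Pipox (2.92, SE 0.96), the apolipoprotein Apoh (2.84, SE 0.96), the glycerol channel Aqp9 (2.71, SE 0.98) and the retinol dehydrogenase Rdh7 (2.69, SE 0.92). Cyp7a1 lay at 11.15 on the first 50 mg/kg array, the highest in hepatocyte transcripts, and at 7.41 on the second, which was low in them. Over the alternative fits the lowest differences of these genes ran from 0.51 for Aqp9 to 0.90 for Pipox. Adgrg2, an adhesion receptor of the epididymis (3.14, SE 1.19), was also among the 10 highest, and its SD of 3.17 at this dose shows that 1 array carried most of it. Errfi1, a feedback inhibitor of the EGF receptor and a glucocorticoid target, differed with less spread (9.89 ± 0.88 to 12.74 ± 0.23).

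**Figure D2:**
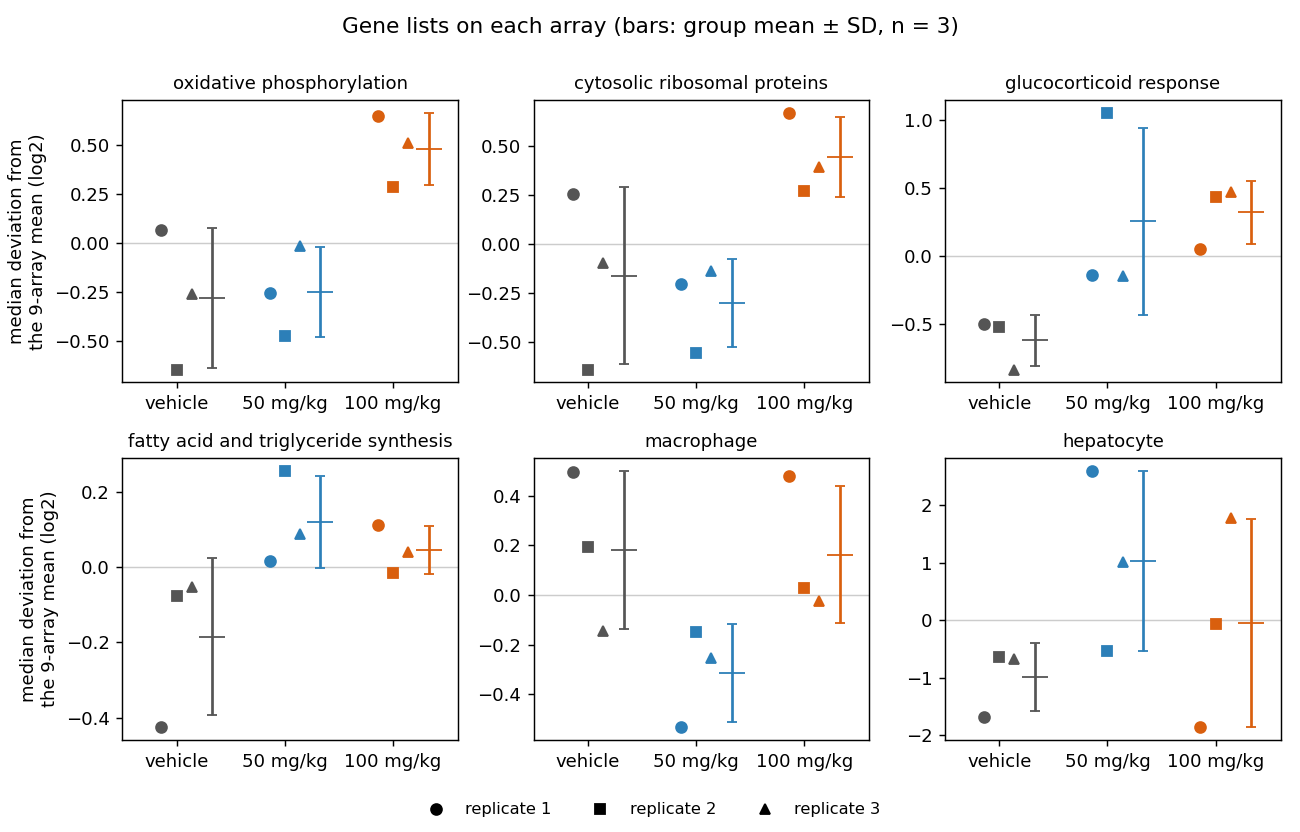
Median deviation of 6 gene lists on each array from the mean of all 9 arrays, with the mean and SD of each group (n = 3).

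Fatty acid and triglyceride synthesis was higher at 50 mg/kg by a median of 0.42 (adjusted p = 2.2e-05, adjusted p = 0.0783 with an estimated correlation, and 0.0139 by fry). Of 23 genes 6 met the study criteria and 1 adjusted over the list alone, led by the elongase Elovl6 (2.19, SE 0.50), the acyltransferase Gpam (0.76, SE 0.26), the phosphatidate phosphatase Lpin1 (0.78, SE 0.29) and acetyl-CoA carboxylase Acaca (0.72, SE 0.27). Glucocorticoid-induced genes had a median of 0.79 (adjusted p = 1.56e-06, adjusted p = 0.381 with an estimated correlation), 7 higher and 1 lower of 18 by the study criteria and 1 adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor (1.32, SE 0.40), the mTORC1 inhibitor Ddit4 (1.28, SE 0.43) and the leucine zipper protein Tsc22d3 (1.02, SE 0.36) were among them.

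Macrophage genes were lower by a median of -0.49 (adjusted p = 3.4e-06, adjusted p = 0.381 with an estimated correlation), 9 of 30 by the study criteria and none adjusted over the list alone. These included the Fc receptor chain Fcer1g (-1.05, SE 0.30), the lectin Lgals3 (-1.44, SE 0.45), lysozyme Lyz2 (-0.80, SE 0.28) and the membrane protein Ms4a7 (-0.84, SE 0.30). The lipid-associated macrophage list shares genes such as Lgals3 and Trem2 with the macrophage list, so the lists are not independent. It had a median of -0.46 (adjusted p = 6.43e-05, adjusted p = 0.686 with an estimated correlation), with 5 of 19 genes by the study criteria, among them the fatty acid binding protein Fabp5 (-1.37, SE 0.45).

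Circadian clock genes had a median of 0.46 (adjusted p = 5.27e-05, adjusted p = 0.381 with an estimated correlation), with 6 of 19 by the study criteria and 2 adjusted over the list alone. The deubiquitinase Usp2 (1.38, SE 0.28) and the period genes Per3 (1.16, SE 0.32) and Per1 (1.38, SE 0.49) led them. Mesothelial genes had a median of 0.55 (adjusted p = 0.000533, adjusted p = 0.938 with an estimated correlation), with 1 of 19 by the study criteria. Fatty acid oxidation had a median of 0.22 (adjusted p = 0.0122, adjusted p = 0.381 with an estimated correlation; 4 of 24, led by Etfdh, which feeds electrons into the chain, 0.73, SE 0.22). Insulin signalling had 0.18 (adjusted p = 0.015, adjusted p = 0.754 with an estimated correlation), with 3 of 25 by the study criteria, among them Foxo1, a transcription factor that insulin restrains (1.18, SE 0.34), and the kinase Akt2 (0.68, SE 0.27).

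Lower at 50 mg/kg with all 3 arrays below vehicle were, besides Lgals3 and Fabp5, the stress gene Gadd45a (-1.49, SE 0.30), the lipase inhibitor Angptl4 (-1.25, SE 0.50), the monocyte attractant Ccl2 (-1.21, SE 0.53), the SUMO protease Senp3 (-1.21, SE 0.41) and the survival factor Bcl2a1a (-1.18, SE 0.34). Dusp10 (-1.11, SE 0.23), the tight junction protein Cldn5 (2.14-fold lower) and the peroxidase Gpx7 (-1.06, SE 0.31) completed them. Groups did not overlap for 12.4% of probe sets, where 10% is chance. Single vehicle arrays weighed on some of these: without the first, the difference was -0.73 for Fabp5, -0.66 for Senp3 and -0.70 for Gpx7.

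Of the 9 lists called at 50 mg/kg, 4 were lost without some single array. Without the first 50 mg/kg array, the highest in hepatocyte transcripts, the mesothelial median was 0.07 (adjusted p = 0.635) and that of lipid-associated macrophages -0.15 (0.0688), while the hepatocyte median was 1.03 (0.000136). The mesothelial list was also lost without the second vehicle array (0.165). Without the second 50 mg/kg array, insulin signalling was lost (0.06, 0.542), and glucocorticoid genes (0.23, 0.0115) and lipid synthesis (0.24, 0.000354) had smaller medians. Insulin signalling was also lost without the first vehicle array (0.146) and fatty acid oxidation without the third 50 mg/kg array (0.127). Without the first 50 mg/kg array the difference was 1.80 for Aqp9 and 1.38 for Adgrg2.

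Between the doses, 30 probe sets rose from 50 to 100 mg/kg and none fell. Myeov2 led again (10.42 ± 0.41 to 14.19 ± 0.10, 13.6-fold, adjusted p = 0.000308). Ndufb9 (2.97, SE 0.41), Atp5g1 (2.69, SE 0.36), Mrpl33 (2.50, SE 0.30), Ppdpf (2.47, SE 0.26), Ndufc1 (2.38, SE 0.25) and Minos1 (2.29, SE 0.23) rose here too. Fcer1g, which macrophages use to signal from Fc receptors, rose from 11.55 ± 0.24 to 14.19 ± 0.09 (6.23-fold, adjusted p = 0.00969). Naa38, an auxiliary subunit of the NatC acetyltransferase (2.42, SE 0.25), and the membrane protein Emp3 (2.41, SE 0.34) were the other 2 of the 10 largest. Of 21 alternative fits, Myeov2, Minos1, Ppdpf, Ndufc1 and Naa38 kept their call in 19, Fcer1g in 17 and Mrpl33 in 16. Atp5g1 kept it in 15, and Ndufb9 and Emp3 in 12.

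Macrophage genes were higher at 100 than at 50 mg/kg by a median of 0.50 (adjusted p = 4.39e-06, adjusted p = 0.580 with an estimated correlation), 8 of 30 by the study criteria and 4 adjusted over the list alone. For lipid-associated macrophage genes, some of them also in the macrophage list, the median was 0.62 (adjusted p = 2.09e-06, adjusted p = 0.580 with an estimated correlation), with 7 of 19 by the study criteria and 6 adjusted over the list alone. The lipid receptor Trem2 (2.20, SE 0.40, adjusted p = 0.0718), Lgals3 (2.11, SE 0.45, adjusted p = 0.132) and the signalling adaptor Tyrobp (1.44, SE 0.38) stood out. Against vehicle, both lists had a median of 0.06 at 100 mg/kg (adjusted p = 0.774 and 0.353).

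Oxidative phosphorylation differed between the doses by 0.63 (adjusted p = 6.51e-19, adjusted p = 0.580 with an estimated correlation), with 21 of 42 genes higher by the study criteria, 3 at adjusted p < 0.05 and 17 adjusted over the list alone. Ribosomal proteins differed by 0.68 (adjusted p = 1.57e-11, adjusted p = 0.580 with an estimated correlation), 15 higher and 1 lower of 30, and 14 higher and 1 lower adjusted over the list alone. Branched-chain amino acid breakdown was higher by 0.16 (adjusted p = 0.000323, adjusted p = 0.580 with an estimated correlation; 5 of 21, 3 adjusted over the list alone). Antioxidant genes were higher by 0.23 (adjusted p = 0.00604, adjusted p = 0.828 with an estimated correlation; 6 of 30, 3 adjusted over the list alone).

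Mesothelial genes were lower at 100 than at 50 mg/kg by a median of -0.86 (adjusted p = 6.01e-05, adjusted p = 0.828 with an estimated correlation; 1 of 19), as were hepatocyte genes by -0.86 (adjusted p = 0.00104, adjusted p = 0.941 with an estimated correlation; 2 of 21). Circadian genes had -0.26 (adjusted p = 0.0299, adjusted p = 0.828 with an estimated correlation), with 1 higher and 2 lower of 19. Immediate early genes had -0.43 (adjusted p = 0.0299, adjusted p = 0.941 with an estimated correlation), with 2 higher and 2 lower of 27, and turned without the second 50 mg/kg array.

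Of the 10 lists called between the doses, 5 were lost without some single array: mesothelial, hepatocyte, circadian, immediate early and antioxidant genes. Without the first 50 mg/kg array the medians were -0.25 for mesothelial (adjusted p = 0.27), -0.39 for hepatocyte (0.388), 0.23 for macrophage (0.000768) and 0.30 for lipid-associated macrophage genes (0.00318). Antioxidant genes had a median of 0.00 without the third 100 mg/kg array (0.796), and circadian genes were lost when each of 4 arrays was left out in turn (adjusted p up to 0.302).

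Among the largest lower transcripts that met the study criteria were the complement protein C7 (-2.63, SE 0.98), the neurotrophic receptor Gfra2 (-2.00, SE 0.46), the Wnt antagonist Sfrp1 (-1.72, SE 0.46), the matrix protein Mfap4 (-1.63, SE 0.53) and the cytochrome Cyp2b13 (-1.60, SE 0.50). The co-chaperone Dnaja4 (-1.56, SE 0.56), the adhesion protein Ceacam1 (-1.54, SE 0.32), the acyl-CoA synthetase Acsbg1 (-1.46, SE 0.65) and the chloride cotransporter Slc12a2 (-1.35, SE 0.38) followed, none past adjustment. Without the first 50 mg/kg array the difference was -0.45 for Acsbg1, -0.70 for Dnaja4, -0.86 for Slc12a2 and -1.03 for Mfap4, and without the first 100 mg/kg array -0.99 for Cyp2b13. By the study criteria 1167 probe sets were higher and 685 lower (1453 over 1.5-fold; 63.0% higher, and 70.4% of the 1190 left without dim probe sets), and groups did not overlap for 15.2% where 10% is chance. The 30 calls became 145 without the first vehicle array and 7 to 14 without any array of the 2 doses.

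The mean of both doses gave 1 call against vehicle, Myeov2 (adjusted p = 0.00271), beside 734 higher and 853 lower probe sets by the study criteria (846 over 1.5-fold). Higher ones were 46.3% of all and 75.0% of the 661 left without dim probe sets. Of 14 lists called, 12 were higher: glucocorticoid 0.82 (adjusted p = 5.3e-09), oxidative phosphorylation 0.42 (7.71e-10), hepatocyte 1.32 (2.37e-07), lipid synthesis 0.27 (0.000128), fatty acid oxidation 0.24 (0.000139), ribosomal 0.19 (0.000139), circadian 0.32 (0.00121), branched-chain 0.22 (0.00472), adipocyte identity 0.16 (0.0105), antioxidant 0.20 (0.0302), insulin signalling 0.14 (0.0358) and heat shock 0.20 (0.0436). Macrophage genes (-0.24, 0.0302) and epididymis genes (-0.20, 0.043) were lower. None passed with an estimated correlation, the lowest being adjusted p = 0.0980 for lipid synthesis and fatty acid oxidation. By fry, lipid synthesis passed (adjusted p = 0.0194). Only the lipid synthesis, fatty acid oxidation, oxidative phosphorylation, hepatocyte and glucocorticoid lists stayed called without each single array, and the ribosomal median was 0.03 without the second vehicle array (adjusted p = 0.563). Any difference among the 3 groups was found for 37 probe sets (lowest adjusted p = 8.9e-05) and, unadjusted, for 1839, and 33 of the 40 calls at 100 mg/kg were among the 37.

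Fold changes at the 2 doses correlated with r = 0.454, where unchanged groups sharing 3 controls gave 0.501 (0.478 to 0.526 in 100 simulations). The probe sets were simulated as independent, whereas real ones vary together. Over the fits leaving out single arrays r had an SD of 0.085, so the simulated range is too narrow to judge a departure from it. The covariance of the fold changes was 0.0669 against 0.0450 simulated, a difference of 0.0218. Probe sets higher at both doses by the study criteria numbered 118 (31.9 for independent lists, 119 simulated), lower at both 264 (29.0 and 122), and opposite 12 (2.71 simulated). In these simulations the shared vehicle arrays alone gave the whole excess over independent lists for probe sets higher at both doses. They gave part of it for those lower at both. Whether the rest exceeds chance cannot be told, since the simulated probe sets were independent. Of the 38 probe sets that rose at 100 mg/kg against vehicle, 25 also rose against 50 mg/kg, which uses the same 100 mg/kg arrays.

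**Figure D3:**
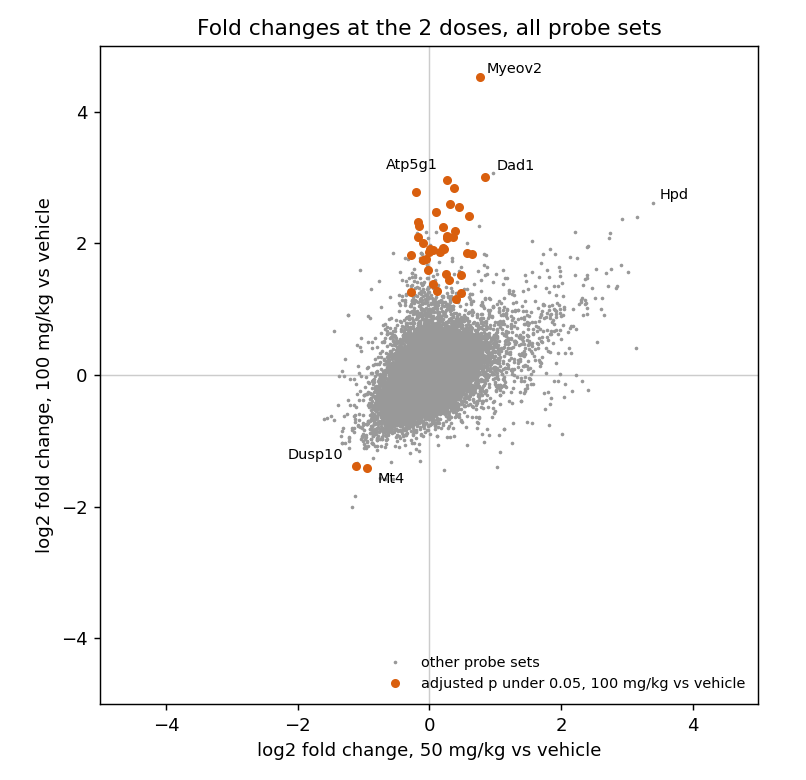
Log2 fold change against vehicle at 50 and at 100 mg/kg for all probe sets, with the 40 called at 100 mg/kg in colour and 6 genes named.

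None of the 17 genes always reported passed adjusted p < 0.05 in any comparison. By the study criteria the adipokine Adipoq was higher at 100 mg/kg (18.70 ± 0.28 to 19.20 ± 0.06; 0.50, SE 0.20) and at 50 mg/kg Ccl2 was lower. The cytokine Tnf met the criteria at both doses and the uncoupling protein Ucp1 at 50 mg/kg, but their signals in vehicle (5.21 ± 0.19 and 4.57 ± 0.29) were already at or below the level of the negative controls, so neither can be read as lower expression. From 50 to 100 mg/kg Adipoq (0.64, SE 0.20), the glucose carrier Slc2a4 (0.86, SE 0.37; 0.52 without the third 50 mg/kg array) and the macrophage marker Cd68 (1.22, SE 0.46) were higher. Lep, Pparg, Fasn, Scd1, Lipe, Pnpla2, Ppargc1a, Adgre1, Il6, Col1a1 and Col6a3 met the study criteria in no comparison. Adipoq, Scd1 (19.91 ± 0.02 in vehicle) and Lep (19.04 ± 0.27) lay at or near the top of the scale of 19.92, where differences are compressed.

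The other lists passed in no comparison. At 100 mg/kg against vehicle the metabolic ones had medians of 0.08 for lipolysis (adjusted p = 0.39), 0.01 for thermogenic and beige adipocytes (0.894), 0.21 for the tricarboxylic acid cycle (0.0863), 0.26 for glycolysis (0.113), 0.06 for adipokines (0.0944) and -0.11 for cholesterol synthesis (0.839). Immune ones had -0.17 for cytokines and chemokines (0.53), -0.07 for alternatively activated macrophages (0.839), 0.02 for interferon response (0.839), -0.05 for T and natural killer cells (0.839), -0.01 for B and plasma cells (0.784), -0.06 for neutrophils (0.639) and 0.09 for mast cells and eosinophils (0.774). Stromal ones had -0.06 for extracellular matrix (0.575), -0.16 for progenitors and fibroblasts (0.774) and -0.02 for endothelium (0.853). Neighbouring tissues had -0.08 for muscle (0.774), 0.01 for mammary and skin epithelium (0.991), -0.11 for pancreatic acini (0.113), -0.04 for neurons and Schwann cells (0.774) and 0.00 for erythrocytes (0.784). Cell cycle genes had -0.04 (0.774) and endoplasmic reticulum stress genes 0.00 (0.562).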

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

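The tests named here as chosen after the result was seen are the matched test of ribosomal genes, the macrophage test for the respiratory chain, the share of choices of 3 arrays, and both tests of the lipid synthesis genes; 3 of the tests replaced others and 2 were read anew, as given below.

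The effects of the 2 doses differed from each other in a direct test, limma's contrast of 100 with 50 mg/kg, and this is what singles them out here. It found 30 probe sets and, at the preset correlation, 10 gene lists at adjusted p < 0.05. None of the lists passed with an estimated correlation (lowest adjusted p = 0.580) or by fry (0.284). The differences of the effects were 3.77 for Myeov2, 2.97 for Ndufb9, 2.69 for Atp5g1, 2.64 for Fcer1g, 2.50 for Mrpl33, 2.47 for Ppdpf, 2.42 for Naa38, 2.41 for Emp3, 2.38 for Ndufc1 and 2.29 for Minos1, all higher at 100 mg/kg.

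Respiratory chain transcripts were higher at 100 mg/kg, together with other short genes. The list's median of 0.68 lay at percentile 100 of random lists matched on span and level (0.02 to 0.38). On these arrays, genes of like genomic span and level thus shifted less than the list. The matched lists were drawn gene by gene, while genes of a list vary together, so the percentile does not measure the spread between arrays. A trend with transcript length was not tested. For ribosomal proteins the trend with genomic span stays open, since their median of 0.58 lay at percentile 86.2 (matched lists 0.09 to 0.74). The respiratory chain and ribosomal lists stayed called at the preset correlation with that trend removed from each array. Matched lists were also drawn for 2 other lists called at 100 mg/kg, with no reading set in advance. Antioxidant genes (0.22) lay at percentile 87.1 (-0.03 to 0.32) and adipocyte identity genes (0.18) at percentile 82.2 (-0.05 to 0.31). Genes of like span and level thus shifted about as much as these 2 lists. A higher share of adipocytes, which would lower the transcripts of all other cells, stays open for the difference between the doses. The macrophage median was higher by 0.50 (bootstrap over genes 0.28 to 0.62, 0.23 without replicate 1 at 50 mg/kg, adjusted p = 0.580 with an estimated correlation). But mesothelial (-0.86) and fibroblast genes (-0.17) lay lower. The mesothelial value leaned on replicate 1 at 50 mg/kg (1.43, against -0.29 and 0.27 on the other arrays of that dose). The fibroblast list passed in no comparison, and by group mean of the array medians it went only from 0.02 to -0.02. By that measure T and natural killer (-0.05 to 0.11) and endothelial genes (-0.10 to -0.02) lay higher. Mast cell and eosinophil (0.03 to -0.02), B and plasma cell (-0.01 to -0.03) and neutrophil genes (-0.03 to -0.04) lay lower, none of these lists called. Adipocyte identity differed by a median of 0.07, with some markers at the top of the scale, against 0.63 for oxidative phosphorylation. Replicate 1 of vehicle, whose removal gave 185 calls, shared the excess of short over long genes, taken among genes of high mean signal (0.54, against 0.23 to 0.49 at 100 mg/kg and -0.39 and -0.35 on the other vehicle arrays). That array also had the highest vehicle medians of oxidative phosphorylation (0.07, against 0.29 to 0.65 at 100 mg/kg) and ribosomal genes (0.25, against 0.27 to 0.67). RNA quality, which would also move these lists outside the dose, and an effect of the dose could each still underlie the difference, and neither was tested.

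Hepatocyte transcripts were high in 3 arrays, replicates 1 and 3 at 50 mg/kg and replicate 3 at 100 mg/kg. A second set of 22 measured liver genes put the same 3 arrays highest (3 of 3), and in 20 of these 22 genes exactly these arrays were the top ones. For a single gene chance gives a share of 0.0119, but liver genes vary together, so the 20 genes are not independent. Liver RNA in the samples would give this, and so would any cause that moves liver genes together. Expression of liver genes by adipose cells themselves cannot be separated from it, since the second set would rank the arrays alike. All 3 arrays came from treated mice, and a share of 0.238 of all choices of 3 arrays are treated only, so whether the extract played a part cannot be told apart from chance with 9 arrays.

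Fatty acid and triglyceride synthesis genes were higher at 50 mg/kg, by less without replicate 2 of that dose (0.24). With the hepatocyte level in the fit the list's median was 0.50, against 0.42 without it, and its adjusted p by camera 5.72e-06 at the preset correlation. The median thus did not shrink, as it would with liver RNA as the whole cause. But that p-value does not measure the spread between arrays. At 50 mg/kg only replicate 2 was low in hepatocyte transcripts (-0.53, against 2.59 and 1.01), so liver RNA is not excluded. With an estimated correlation the list had not passed even without that term (adjusted p = 0.0783). Fewer macrophages, and so a larger adipocyte share, stays open: synthesis genes exceeded adipocyte identity genes by 0.26, but the bootstrap interval of -0.02 to 0.52 holds 0. Adipocyte identity had a median of 0.16 (-0.04 to 0.34), and an effect of the extract on lipid synthesis was not tested apart from these.

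Besides, 5 tests were replaced or read differently once their values were known, because each rested on weak ground. Oxidative phosphorylation minus adipocyte identity at 100 mg/kg was 0.50 (0.09 to 0.82), read at first as arguing against more adipocytes, and was replaced because some adipocyte markers lie at the top of the scale. In hepatocyte transcripts 5 treated arrays exceeded the highest vehicle array (-0.63), read at first against an effect in every animal, which rested on 1 array. Synthesis genes on replicate 2 at 50 mg/kg, low in hepatocyte transcripts, lay at 0.26 (highest vehicle array -0.05), read at first against liver RNA, which also rested on 1 array. The value of 0.26 for synthesis minus adipocyte identity was at first counted for fewer macrophages and is now left open. Likewise the macrophage median of 0.50 was at first read against more adipocytes, but its interval is over genes and not over arrays.

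Other splits of the arrays were counted for each number of calls. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. At 50 mg/kg, 10 of 10 splits gave at least 0 adjusted calls (highest other 0), 1 gave as many as the 1582 by the study criteria (highest other 1382) and 4 gave as many as 9 lists (highest other 13). At 100 mg/kg the numbers were 1 for 40 calls (highest other 0), 1 for 1726 (highest other 1663) and 5 for 9 lists (highest other 14). Between the doses they were 2 for 30 calls (highest other 227), 1 for 1852 (highest other 1255) and 8 for 10 lists (highest other 15).

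For both doses against vehicle, 8 of 84 splits gave at least 1 call (highest other 305), 12 gave 1587 by the study criteria (highest other 2424) and 9 gave 14 lists (highest other 18), so chance is not excluded for any of the 3 numbers. The splits with 227 and 305 calls set replicates 1 and 3 at 50 mg/kg and replicate 3 at 100 mg/kg apart, the arrays of high hepatocyte signal, and point to a structure of the samples other than the dose. For any difference among the 3 groups, 9 of 100 splits drawn from 280 gave at least 37 adjusted calls (highest other 267), so chance is not excluded. For the 1839 unadjusted ones it was 1 of 100 (highest other 1781). Earlier draws, moved by unrelated changes to the code, had given 5 and then 4 of 100, on both sides of a share of 0.05, so the share depends on the draw and chance is not taken as excluded here either.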

How the results depend on the processing

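The tests chosen after the data were seen are the 3 alternatives of the hepatocyte level, the 3 arrays left out and the span trend. The number of arrays, 3 per group, limits the precision, and differences near the negative controls or at the top of the scale cannot be measured well. Of the comparisons of overall counts and correlations with an alternative 246 stayed and 69 moved; of single lists 702 stayed, 197 weakened and 11 reversed; of named genes 2659 stayed, 709 weakened, 14 strengthened, 2 moved and 1 reversed. Myeov2 at 100 mg/kg against vehicle passed in all 21 alternatives (adjusted p 5.45e-06 to 0.0478), Minos1 in 20, Dad1, Ppdpf and Ndufc1 in 19, Atp5g1 in 16, Mrpl33 in 14, Atp5d in 12, Ndufb9 in 10, Rpl28 in 8, Mt4 in 6 and Dusp10 in 4, none changing sign. Where nothing else is said, the cause was not tested.

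Without dim probe sets, fewer being tested, the study criteria gave 681 at 50 mg/kg, 911 at 100 mg/kg, 1190 between the doses and 661 for both, and 1014 passed the F test unadjusted. Lists called were then 5 at 100 mg/kg and 9 for both doses, and the epididymis list reversed (adjusted p = 0.723). Quantile normalization gave 20 calls and 4 lists at 100 mg/kg, 8 lists for both doses and 20 by the F test.

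Fitted on their own groups alone, with fewer arrays to estimate the spread, 100 mg/kg against vehicle gave 10 calls and the 2 doses 125. Moderation with trend and robust fitting gave 46 between the doses. Array weights gave 66 at 100 mg/kg, 82 between the doses and 60 by the F test. Without moderation the counts were 1 at 100 mg/kg, 0 between the doses, 0 for both and 0 by the F test. A fold over 1.5 left 846 for both doses, by construction. A block of replicate numbers gave 3 calls for both doses, though the numbers are not known to pair the arrays. Of 9 arrays 4 correlated best with their own number, which does not decide it.

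With an estimated correlation camera called 0 lists at 50 mg/kg, 0 at 100 mg/kg, 0 between the doses and 0 for both. Fry called 1, 0, 0 and 1.

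Leaving out single arrays gave 9 to 185 calls at 100 mg/kg, 7 to 145 between the doses and 1 to 5 for both doses, the highest each time without the first vehicle array. Lists for both doses numbered 9 to 14, the lowest without the third 100 mg/kg array, and F test calls 3 to 146. The correlation of the doses ranged from 0.314 without the third 100 mg/kg array to 0.568 without the second vehicle array (0.558 without the third). Reversed were the hepatocyte list at 100 mg/kg without the third array of that dose (adjusted p = 0.9995; 1.61e-08 without its first) and the immediate early list between the doses without the second 50 mg/kg array (0.459; 1.77e-05 without the third).

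With the hepatocyte level as covariate, 24 probe sets were called at 100 mg/kg and 18 between the doses. The hepatocyte list reversed by construction (adjusted p = 0.333 at 50 mg/kg, 0.774 at 100 mg/kg, 0.744 between the doses and 0.441 for both), and so did the mesothelial list at 50 mg/kg (0.649) and the antioxidant list for both doses (0.881). Leaving out the 3 arrays of high hepatocyte signal leaves 1 array at 50 mg/kg, so that each value of that dose rests on 1 sample and the other groups supply the spread. It gave 893 by the study criteria at 50 mg/kg, 2 calls at 100 mg/kg, 0 calls and 954 by the study criteria between the doses, 0 calls for both, 1 call and 1031 unadjusted by the F test, and a correlation of 0.328. Fewer arrays enter these. Reversed, on that 1 sample for all but the hepatocyte list, were the mesothelial list at 50 mg/kg (0.621), the hepatocyte list at 100 mg/kg (0.960) and Slc2a4 between the doses (-0.13). With the span trend removed, 41 and 39 probe sets were called at 100 mg/kg against vehicle and between the doses.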

Other observations

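The tests of the deposited tables below were chosen after the data were seen. In the authors' deposited table of 100 mg/kg against vehicle, 1240 probe sets are listed, 719 higher and 521 lower, 27 of them at an FDR under 0.05 and with folds down to 1.11. Myeov2 has a fold of 20.98 there (FDR 0.0006), Atp5g1 6.65, Dad1 5.51 and Retn 5.17, while Dusp10 has -1.81 and Mt4 -2.02. Of the 1240, 1239 had the same direction in the fit used here, 962 met the study criteria there, and all 40 calls were among them. In a fit of the workbook's own signals 1212 met them.

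The authors' deposited table of all 3 groups gives an FDR under 0.05 for 3832 probe sets and p under 0.05 for 6849, with the lowest p of 1.03e-11 for the Wnt antagonist Sfrp5, a gene chosen here after its values were seen. A limma fit of the signals in the same workbook gave 29 adjusted and 1946 unadjusted calls, with p = 0.701 for Sfrp5, and its p-values had a rank correlation of 0.430 with those deposited. The labels name a one-way analysis of variance with empirical Bayes, but the deposited p-values do not follow from the sheet, and whether other arrays entered that model is not stated.

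The workbook's columns called Ob 2 and Ob 1 matched the first and second vehicle arrays of the series, with correlations of deviations of 0.943 and 0.916, so the vehicle numbers differ between the deposited files. The first 2 axes of a principal component analysis held 27.0% and 16.7% of the variance.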
